A study of Mus musculus with 6 samples.

How the data were processed

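Liver RNA from 6 samples of mice fasted for 6 h was sequenced, 3 labelled as controls and 3 labelled as having TOX3 activated. The table deposited by the authors held expected counts, which are estimated read counts that need not be whole, for 22322 genes with Ensembl identifiers. Per the submitters' processing notes, Bowtie2, RSEM and DESeq2 were used with the mouse genome build mm10, with no versions or roles stated. RSEM shares reads that match several genes between them by an estimated probability, so close paralogs can trade counts. Per library, 7.01% to 7.64% of the values were not whole numbers. Total counts were 21411828, 23065117 and 17026580 in controls 1 to 3 and 23787465, 20796514 and 21940768 in TOX3-activated libraries 1 to 3. A count of 3, about the upper 95% limit behind a count of 0, corresponded to 0.126 to 0.176 CPM, the depth-scaled counts of edgeR. Such limits and intervals cover counting error only. The gene annotation behind the counts, the strandedness of the libraries and the means of activation are not given in the sources used here.

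Each sample took its group from the genotype label, and its column from the title number that it shares. The replicate numbers 1 to 3 are names given in listing order and pair no samples. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom lay between 12.3 and 77.0 for every pair, so no 2 were repeat reads of the same library, which does not show that they came from separate animals. Symbols and positions came from GENCODE release M21 on the matching build, which held 22267 of the identifiers. The other 55 stayed in the tests without a symbol.

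Expected counts were rounded to whole numbers. Genes too low for a test were removed with the default expression filter of edgeR 4.0.16 in R 4.3.3, which left 12674 genes. Libraries were scaled by the trimmed mean of M values (TMM), and the groups were compared with edgeR's quasi-likelihood F test, two-sided, as TOX3-activated minus control. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. CPM values in the text are TMM-scaled and given as mean ± SD over 3 libraries, and the standard error (SE) of a log2 fold change is its size divided by the square root of F. Comparisons of single library measures used exact two-sided permutation tests, which cannot give a p below 0.1 with 3 against 3.

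Before the data were examined, 34 gene lists were fixed from general knowledge of liver biology, together with the design, the alternatives and the rule for named genes. Lists with at least 3 tested members, 33 in all, were tested on log2 CPM (prior count 2) with camera from limma 3.58.1, at a preset correlation between genes of 0.01, and adjusted over the lists. Camera asks whether a list's genes moved more than other genes. The same test with an estimated correlation and the rotation test fry were run beside it. Within each list, the gene p-values were also adjusted over the list alone. Some lists share members, so their results are not independent. Pck1 and G6pc, for example, are in the gluconeogenic, FoxO1-induced and periportal lists. The rule named 11 genes whatever their result, the 10 largest rises and the 10 largest falls among genes that passed without overlap between groups and reached 1 CPM in a group, and up to 4 members with the lowest p of each list that passed or held a gene that passed. Unnamed gene models and pseudogenes were left out of the largest changes. This gave 108 genes. Cd163, Marco, Ighm, Igkc and Ddx3y lie outside the rule and were chosen from the lists after their values were seen.

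The alternatives changed 1 choice at a time, except that the DESeq2 test came with its own scaling: DESeq2-type size factors, library totals without TMM, no filter beyond a count above 0, a filter of 5 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, voom with quality weights, a fold threshold of 1.5, the set tests above, and leaving out each library. Another quasi-likelihood estimator in edgeR and a correction for GC content and transcript length were added after seeing the data. The fits were tested on simulated data in 5 draws over 12674 genes, with 200 genes changed in each and the fitted spread of this comparison. The main test recovered 5.9% of genes changed 1.25-fold, 35.7% at 1.5-fold, 74.4% at 2-fold and 95.6% at 4-fold with the spread estimated gene by gene, and 8.89%, 49.4%, 85.3% and 99.6% with the spread on the mean trend. Of its calls there, 8.21% and 3.67% were false in these settings, against 14.7% and 4.23% for DESeq2. The voom and other quasi-likelihood fits leave the list p-values as they are, since camera ran on the same log2 CPM, and the DESeq2 fit changes only their scaling.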

Results

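Gene expression was measured by RNA sequencing in the livers of mice fasted for 6 h, in 3 control samples and 3 samples labelled TOX3-activated. TOX3 is a nuclear protein of the TOX family, which carries a high mobility group box that binds DNA. The series concerns TOX3, hepatic gluconeogenesis and its regulator FoxO1, and its design names 1 comparison, TOX3-activated against control liver. Library totals ran from 17026580 to 23787465 counts, and 15100 to 15322 genes had a count above 0. The first principal component of the log2 expression values held 39.1% of the variance and placed all 3 control libraries (-25.4, -19.9 and -14.5) on the other side from the TOX3-activated ones (22.4, 26.6 and 10.8).

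Tox3 itself was close to silent in control liver and well expressed in each TOX3-activated library. The gene (ENSMUSG00000043668) lies on the minus strand of chromosome 8, from 90247040 to 90348343 in mm10, and its values were counted over the whole gene. Its level was 0.0626 ± 0.0271 CPM in controls and 16.3 ± 5.33 CPM in TOX3-activated liver (SD, n = 3 each), with single libraries at 21.5, 10.8 and 16.7 CPM. The controls held 4 counts in total and the TOX3-activated libraries 1045, a ratio of 268 after allowing for depth (95% counting interval 104 to 984). The edgeR quasi-likelihood test gave an adjusted p of 5.56e-05, and the exact permutation p was 0.1, the smallest that 3 against 3 allow. Of the other TOX family genes tested, Tox (log2 fold change -0.12, SE 0.22) and Tox4 (-0.011, SE 0.11, with fractional counts in all 6 libraries) did not pass. The 3 tested members, Tox3 among them, had as a list an adjusted p of 0.0679 by camera. Their mean lay above 0 and their median was -0.011, so the mean and median differ in sign. The list passed by fry (0.0087) and with library totals (0.0122). Tox3, the activated gene, was the 1 member above 0, so these passes say nothing about the rest of the family.

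**Figure D1:**
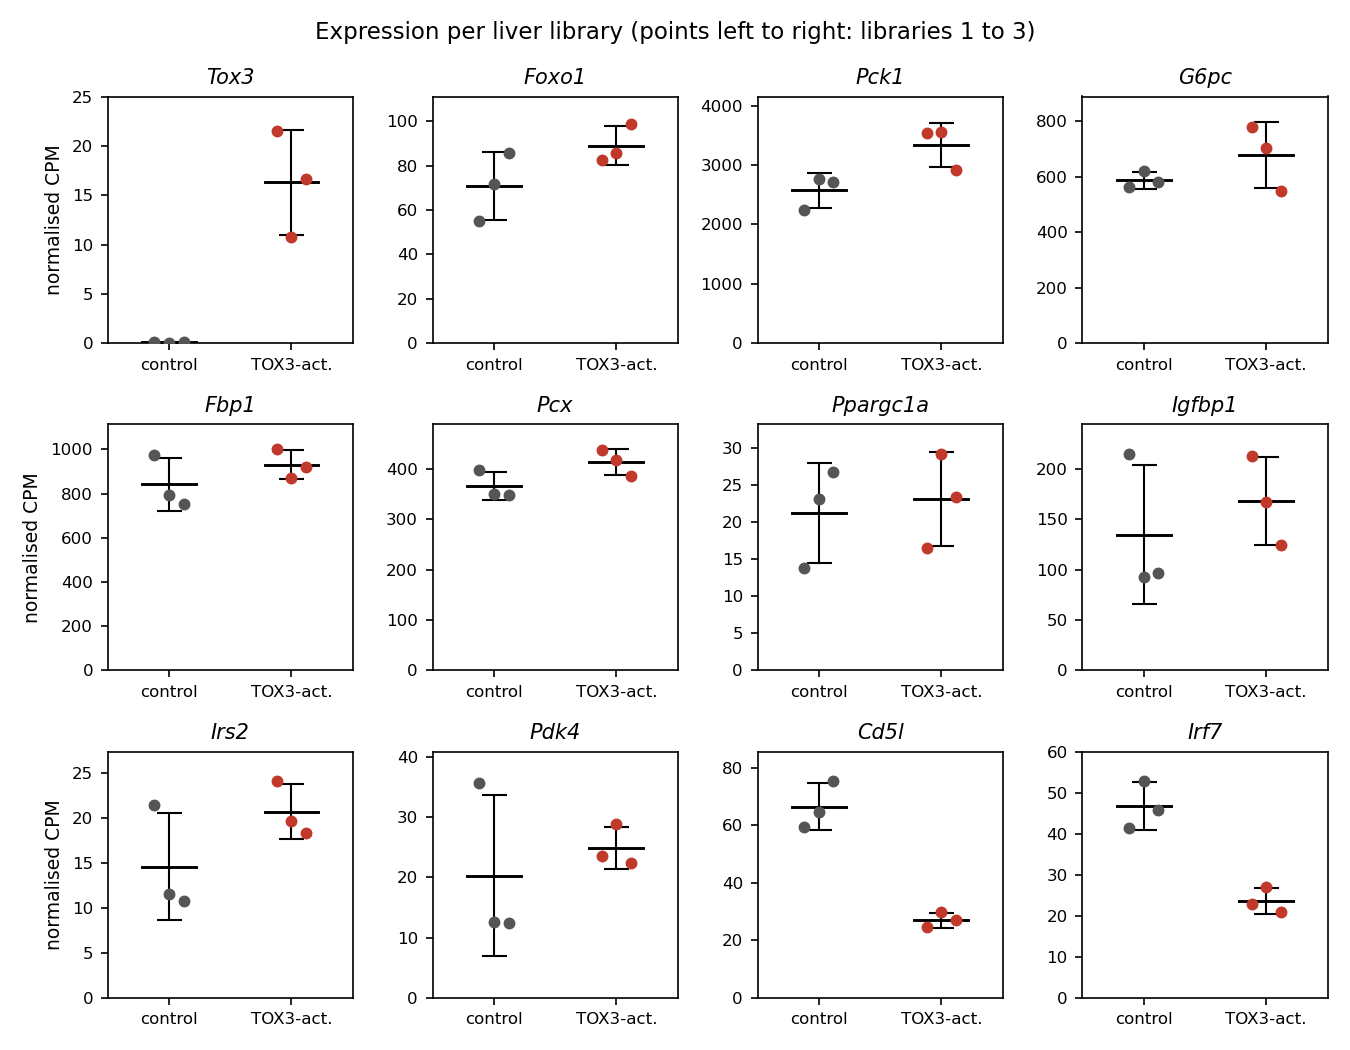
TMM-scaled CPM of 12 genes in each of the 6 liver libraries (y axis from 0, 1 panel per gene); points are libraries 1 to 3 from left to right, the long bar is the group mean and the whiskers are 1 SD. Tox3 lay at 10.8 CPM or more in the TOX3-activated libraries and below 0.1 CPM in controls, Cd5l and Irf7 were lower in all 3 TOX3-activated libraries, and control 1 stood above the other controls for Igfbp1, Irs2 and Pdk4. Control 1 lay below the other controls for Foxo1, Pck1 and Ppargc1a.

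More genes fell than rose when TOX3 was activated. Of 12674 genes tested, 82 rose and 190 fell at an adjusted p below 0.05 (40 and 570 with library totals in place of TMM), and of these 272 genes 18 rose and 87 fell by at least 2-fold. Apart from Tox3, the largest rises were those of Bst1 (4.59-fold), Igfbp6 (4.16-fold), Slc22a28 (3.91-fold), Mrc2 (2.94-fold), Loxl1 (2.76-fold), Ptpn13 (2.70-fold), Igfbp5 (2.59-fold), Hspa1a (2.58-fold) and Ogn (2.54-fold). Igfbp5 and Igfbp6 encode binding proteins of insulin-like growth factors, Loxl1 an enzyme that crosslinks elastin and collagen, Mrc2 a collagen uptake receptor and Ogn a small matrix proteoglycan. Igfbp5 was the most abundant of them, at 16.5 ± 8.01 CPM in controls and 42.3 ± 6.23 CPM in TOX3-activated liver (SD, n = 3 each; adjusted p = 0.0329). Slc22a28 and Hspa1a had fractional counts in all 6 libraries, so part of their counts was shared with close paralogs and their changes are uncertain. The size of the Bst1 rise is uncertain too (adjusted p = 0.0457 by the main test). It rests on 2, 6 and 9 counts in controls 1 to 3 and 23, 28 and 27 in TOX3-activated libraries 1 to 3. Control 1, at 0.0927 CPM, lay below its floor of 0.14 CPM. Without control 3 the log2 fold changes of Bst1 and Igfbp6 were 2.81 and 2.73, against 2.20 and 2.06 with all libraries.

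The largest falls included the cytotoxic granule enzymes Gzma (5.72-fold lower) and Gzmb (4.21-fold), the T cell co-receptor Cd8a (4.50-fold), and the interferon-inducible genes Slfn4 (7.45-fold) and Gbp2b (4.08-fold). Radil (1.07 ± 0.570 CPM in controls, SD, n = 3, and 4, 0 and 2 counts in the TOX3-activated libraries), Obp2a (4.06-fold), Rgs1 (4.03-fold), Bbs12 (3.93-fold) and the myeloid receptor Cd300e (3.93-fold) completed the 10. The size of the Radil fall is uncertain, since its TOX3-activated mean of 0.0914 CPM lay below the floor, and its log2 fold change of -3.40 was -4.27 without TOX3-activated library 1. That of Cd8a was -2.85 without TOX3-activated library 3, against -2.17, and that of Rgs1 -1.41 without control 1, against -2.01. Obp2a, which encodes a lipocalin, had the highest level of these, 47.9 ± 11.9 CPM in controls and 11.8 ± 3.52 CPM in TOX3-activated liver (SD, n = 3 each; log2 fold change -2.02, SE 0.22, adjusted p = 0.00336). The 2 groups did not overlap for any of the 272 genes that passed; over all tested genes 22.2% did not overlap, where chance gives 10%. The number that passed fell to 172, 52 and 152 without controls 1, 2 and 3, and to 65 and 120 without TOX3-activated libraries 1 and 2; it was 341 without TOX3-activated library 3, with 150 that rose and 191 that fell. Of the 10 largest rises 1 passed without control 2, and of the 10 largest falls 4 passed without TOX3-activated library 1.

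**Figure D2:**
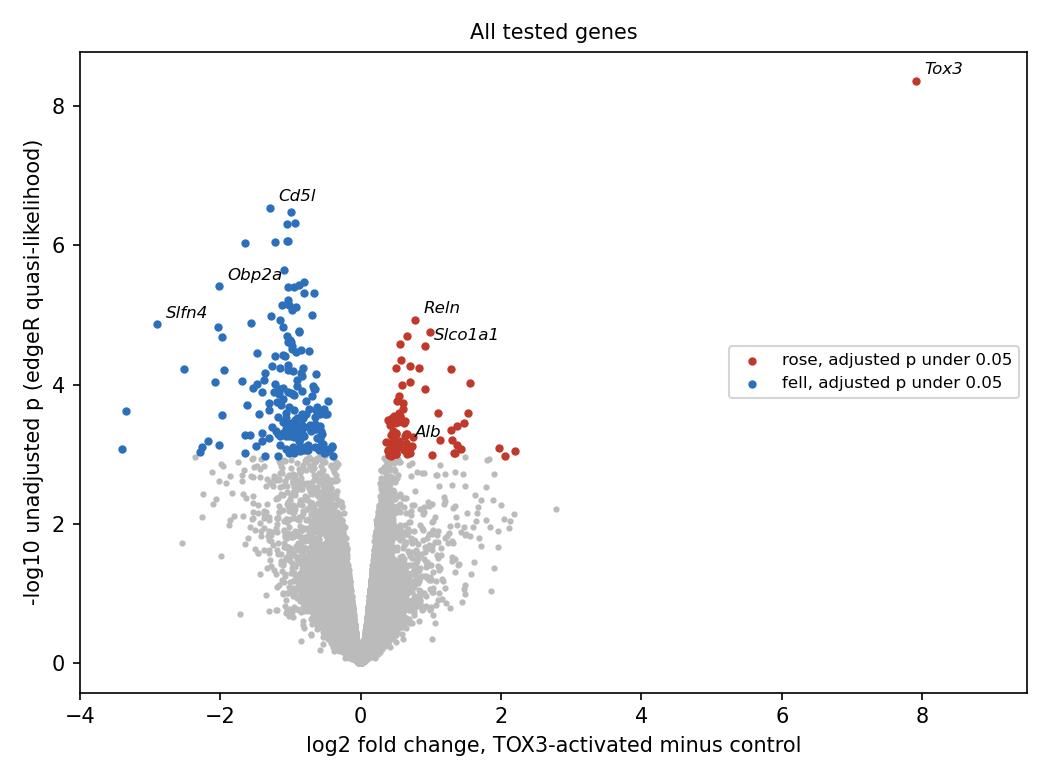
Log2 fold change of TOX3-activated minus control liver (x axis) against -log10 of the unadjusted p of the edgeR quasi-likelihood test (y axis) for the 12674 tested genes. Coloured points passed an adjusted p of 0.05, 82 that rose in red and 190 that fell in blue; Tox3 stands apart at a log2 fold change of 7.92.

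Genes of glucose production, the process named by the series, did not pass the test, and 10 of 15 tested enzymes lay above 0 and 5 below. Pck1 (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273), which encodes the enzyme of the first committed step of gluconeogenesis, was at 2572 ± 289 CPM in controls and 3336 ± 373 CPM in TOX3-activated liver (SD, n = 3 each), with no overlap between groups. Its log2 fold change was 0.38 (SE 0.12, adjusted p = 0.163). G6pc (ENSMUSG00000078650, chromosome 11, 101367561 to 101377903), whose product releases free glucose, was at 587 ± 29.7 and 677 ± 119 CPM (SD, n = 3 each; log2 fold change 0.21, SE 0.13, adjusted p = 0.455). Fbp1 (0.15, SE 0.11) and Pcx (0.18, SE 0.091), which encode further enzymes of the pathway, had adjusted p-values of 0.576 and 0.365. None of 15 gluconeogenic enzyme genes tested passed over all genes, and 0 passed when adjusted over the list alone. The list had a median log2 fold change of 0.12 and an adjusted p of 0.071 by camera (adjusted p = 0.373 with an estimated correlation, and 0.176 by fry). Its adjusted p was 0.0343 without control 1, 0.0445 without TOX3-activated library 3 and 0.0484 with the correction for GC content and length. Its median was 0.047 without TOX3-activated library 1. DESeq2 gave Pck1 an adjusted p of 0.0282. In simulated data with the spread set gene by gene, 14.7% of DESeq2 calls were false, against 8.21% for the main test. With the spread on the mean trend these shares were 4.23% and 3.67%. With library totals in place of TMM, which shifted the median of all genes by -0.15, the list's median was -0.031.

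Foxo1, which encodes the transcription factor FoxO1, and genes known from earlier work to be induced by it did not pass either. Foxo1 (ENSMUSG00000044167, chromosome 3, 52268336 to 52353221) was at 70.8 ± 15.2 CPM in controls and 89.0 ± 8.71 CPM in TOX3-activated liver (SD, n = 3 each; log2 fold change 0.33, SE 0.14, adjusted p = 0.284). Igfbp1 (0.32, SE 0.30, adjusted p = 0.662), Irs2 (0.51, SE 0.23, adjusted p = 0.315), Pdk4 (0.30, SE 0.34, adjusted p = 0.737) and the coactivator Ppargc1a (0.12, SE 0.24, adjusted p = 0.871, and -0.037 with library totals) did not pass. Of 19 FoxO1-induced genes tested, 0 passed over all genes and 0 when adjusted over the list alone; 15 lay above 0 and 4 below. The list's adjusted p was 0.0691 by camera (median log2 fold change 0.12), 0.302 with an estimated correlation and 0.0199 by fry. Control 1 stood apart from the other controls, at 215 CPM against 93.0 and 96.9 CPM for Igfbp1, 35.7 against 12.6 and 12.5 CPM for Pdk4, and 21.4 against 11.5 and 10.8 CPM for Irs2. It was the lowest control for Foxo1 (55.1 against 71.8 and 85.5 CPM) and Ppargc1a (13.8 against 23.2 and 26.8 CPM). Without control 1, Irs2 (log2 fold change 0.88, adjusted p = 0.0221), Pdk4 (0.98, adjusted p = 0.00935) and the list (adjusted p = 0.014) passed, while Igfbp1 did not (0.82, adjusted p = 0.066). The list's median was -0.039 with library totals, where its camera test, which sets it against other genes, gave genes known to be induced by FoxO1 an adjusted p of 0.0251, upward.

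Foxo4, a relative of Foxo1, was the gene that rose among 19 tested regulators of gluconeogenesis, from 8.98 ± 0.557 to 14.0 ± 1.42 CPM (SD, n = 3 each; log2 fold change 0.63, SE 0.12, adjusted p = 0.0302). When adjusted over the list alone it was again the 1 gene that passed. Nr4a1 (log2 fold change -0.66, SE 0.25, adjusted p = 0.221) and Cebpa (0.18, SE 0.089, adjusted p = 0.357) did not pass, and the list had an adjusted p of 0.12 by camera (adjusted p = 0.366 with an estimated correlation), with a median of 0.085 that turned to -0.060 with library totals. Foxo4 missed the threshold without any 1 of controls 1 to 3 or TOX3-activated libraries 1 and 2 (adjusted p up to 0.12) and with library totals (0.0503).

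Markers of Kupffer cells, the resident macrophages of the liver, were mostly lower in TOX3-activated liver, with a median 1.94-fold below control. Of 12 markers tested, 9 fell and 0 rose over all genes, and 10 fell when adjusted over the list alone. Cd5l (chromosome 3, 87357881 to 87371073), a protein secreted by macrophages, went from 66.5 ± 8.12 to 27.1 ± 2.58 CPM (SD, n = 3 each; log2 fold change -1.30, SE 0.11, adjusted p = 0.00126). Csf1r, the receptor for the macrophage growth factor, fell 1.98-fold, and the complement genes C1qb and C1qc fell 1.90-fold and 2.07-fold, each with an adjusted p of 0.00126. Csf1r had fractional counts in all 6 libraries, so its change is uncertain. Cd163, at 2.50 CPM in controls, and Marco, at 2.67 CPM, had log2 fold changes of 0.61 (SE 0.44) and 0.050 (SE 0.40) and did not pass. The list's median log2 fold change was -0.96, with an adjusted p of 2.12e-12 by camera (adjusted p = 0.124 with an estimated correlation) and 0.00359 by fry. In the same libraries Alb took 5.29% ± 0.0581 of the counts in controls and 7.52% ± 0.628 in TOX3-activated liver (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Of the 9 genes, 8 passed in each of the 14 alternative fits.

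Genes induced by interferon were also lower in TOX3-activated liver. All 20 tested members had a log2 fold change below 0; 11 fell over all genes, 17 fell when adjusted over the list alone and 0 rose. Irf7, a transcription factor of the antiviral response, went from 46.9 ± 5.83 to 23.7 ± 3.09 CPM (SD, n = 3 each; log2 fold change -0.98, SE 0.12, adjusted p = 0.00494). Ifi27 fell 1.89-fold (adjusted p = 0.0047) and Ifi44 2.11-fold (adjusted p = 0.00996). Ifit3 fell 2.07-fold (adjusted p = 0.00723), with fractional counts in all 6 libraries. The list's median log2 fold change was -0.87, with an adjusted p of 2.04e-14 by camera (adjusted p = 0.0826 with an estimated correlation) and 0.00306 by fry. Without control 2 only 3 of the 20 genes passed, without control 3 6 did, and without TOX3-activated library 1 4 did; Ifi27, Irf7 and Ifit3 passed in each of the 14 alternative fits.

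Other immune markers were scarce in these libraries and mostly lower in TOX3-activated liver. Of 9 lymphocyte markers tested, Gzma (1.58 ± 0.428 against 0.271 ± 0.0419 CPM; SD, n = 3 each), Gzmb and Cd8a fell, and 6 fell when adjusted over the list alone. Cd3e, part of the T cell receptor complex, had a log2 fold change of -1.96 (SE 0.45, adjusted p = 0.0568), while the antibody genes Ighm (0.35, SE 0.59) and Igkc (0.021, SE 0.43) lay above 0. The lymphocyte list had a median of -1.55 (-0.82 without the expression filter) and an adjusted p of 4.77e-06 by camera (adjusted p = 0.0826 with an estimated correlation). None of 4 neutrophil and monocyte markers passed over all genes and 2 fell when adjusted over the list alone, Csf3r (-1.23, SE 0.30) and Il1b (-2.26, SE 0.68). Il1b was at 5.75 CPM in control 1 against 1.29 and 0.929 CPM in the other controls, and its log2 fold change was -1.02 without control 1. That list passed (median -0.78, adjusted p = 0.0207; adjusted p = 0.243 with an estimated correlation), but not with library totals (0.0623); its median was -1.26 without control 2 and -1.27 without TOX3-activated library 2. Without TOX3-activated library 1 none of the 3 lymphocyte genes passed, and 1 passed without control 2 or TOX3-activated library 2.

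The remaining cell types of the liver moved less and in both directions. All 16 endothelial markers had a log2 fold change below 0 (median -0.27), 0 passed over all genes and 3 fell when adjusted over the list alone, led by the junction gene Cdh5 (-0.51, SE 0.13, adjusted p = 0.0725) and Pecam1 (-0.43, SE 0.11, adjusted p = 0.0856). That list had an adjusted p of 0.000605 (adjusted p = 0.459 with an estimated correlation). In the stellate cell and matrix list Reln, which encodes a secreted glycoprotein made by stellate cells, rose 1.71-fold, from 30.2 ± 2.51 to 51.6 ± 4.92 CPM (SD, n = 3 each; adjusted p = 0.00581), and was the 1 gene of 17 that rose, adjusted over all genes or over the list alone. Lum (0.77, SE 0.27), Pdgfrb (0.44, SE 0.16) and Rgs5 (-0.43, SE 0.13) did not pass, and the list had a median of 0.41 and an adjusted p of 0.0207 (adjusted p = 0.459 with an estimated correlation). Of 6 red blood cell genes 0 passed over all genes and 6 rose when adjusted over the list alone, Hba-a1 among them at 76.8 ± 22.4 and 122 ± 31.4 CPM (SD, n = 3 each); Hba-a1, Hba-a2 and Hbb-bs had fractional counts in all 6 libraries. That list had a median of 0.64 and an adjusted p of 0.00335 (adjusted p = 0.373 with an estimated correlation). The 9 bile duct markers did not pass (median 0.045, adjusted p = 0.596, and a median of -0.10 with library totals). The endothelial list missed the threshold without TOX3-activated library 3 (median -0.16, adjusted p = 0.0752), and the stellate list without control 1 (adjusted p = 0.0992) or TOX3-activated library 2 (median 0.16, adjusted p = 0.139). With library totals the endothelial median was -0.42 and the stellate median 0.26, and without control 1 the red blood cell median was 0.42.

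Genes of hepatocytes, the main cell type, were higher in TOX3-activated liver, and those expressed around the central vein were higher than those near the portal vein. Alb, the serum albumin gene, rose from 50290 ± 1398 to 79140 ± 6111 CPM (SD, n = 3 each; 1.57-fold, adjusted p = 0.0419), and all 12 hepatocyte markers had a log2 fold change above 0, with 1 passing over all genes and 4 when adjusted over the list alone. The list's median was 0.29 (0.14 with library totals; adjusted p = 1.03e-05, or adjusted p = 0.216 with an estimated correlation). Of 15 pericentral genes, Tbx3 (0.55, SE 0.093, adjusted p = 0.0199), Gulo (0.67, SE 0.13, adjusted p = 0.0359) and Cyp1a2 (0.62, SE 0.13, adjusted p = 0.0454) rose, and 11 rose when adjusted over the list alone. Tbx3 encodes a transcription factor, Gulo an enzyme of vitamin C synthesis and Cyp1a2 a cytochrome P450 that metabolises caffeine. The pericentral list had a median of 0.39 (0.24 with library totals; adjusted p = 8.46e-07, or adjusted p = 0.0826 with an estimated correlation), and the 14 periportal genes one of 0.077 (adjusted p = 0.469, and a median of -0.072 with library totals), with 0 passing over all genes or over the list alone. The difference between these medians was 0.315 (permutation p over genes 0.00131, which does not treat samples as replicates). Alb lost its call in 7 of 14 alternative fits, among them those without control 1, 2 or 3 or TOX3-activated library 1 or 2 (adjusted p 0.0631 to 0.147). Without control 1, 2 or 3 or TOX3-activated library 2, 0 of the 15 pericentral genes passed.

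Transport of bile acids and drug metabolism included further rises, though both list medians lay below the hepatocyte marker median of 0.29. Whether a larger hepatocyte share accounts for these rises was not tested. Slco1a1, an uptake transporter of bile acids and other organic anions, rose 1.89-fold to 378 ± 66.3 CPM (SD, n = 3; log2 fold change 0.92, SE 0.13, adjusted p = 0.00855). Slc10a1, the main sodium-dependent bile acid uptake transporter, rose 1.46-fold (adjusted p = 0.0277) and Slc27a5, which conjugates bile acids to coenzyme A, rose 1.48-fold (adjusted p = 0.0287). These were the 3 of 17 bile acid genes that rose over all genes, and 6 rose when adjusted over the list alone (median 0.23, and 0.080 with library totals, adjusted p = 0.000147; adjusted p = 0.129 with an estimated correlation). Of 22 xenobiotic genes Cyp2c50 (1.64-fold), Cyp2c54 (1.55-fold) and Cyp1a2 rose, against 6 that rose and 1 that fell when adjusted over the list alone. Cyp2c50, Cyp2c54 and Gsta1 had fractional counts in all 6 libraries, so their values are uncertain. Gsta1 (log2 fold change -1.99, SE 0.45, adjusted p = 0.0552) did not pass, but did in 4 of 14 alternative fits. The list did not pass (adjusted p = 0.195; adjusted p = 0.558 with an estimated correlation), and its median of -0.031 differed in sign from the upward direction of its test; it passed with library totals (median -0.18, adjusted p = 0.0122). None of the 3 bile acid genes and none of the 3 xenobiotic genes passed without control 2. Without control 1, 1 xenobiotic gene rose and 1 fell. In each list 1 gene rose without control 3, TOX3-activated library 1 or TOX3-activated library 2.

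Metabolic lists moved by small amounts. In the urea cycle and amino acid list, Prodh, which starts proline breakdown, rose 1.31-fold (adjusted p = 0.0449); 1 of 25 genes passed over all genes and 4 when adjusted over the list alone (median 0.14, adjusted p = 0.000605; adjusted p = 0.373 with an estimated correlation). Among 17 fatty acid and triglyceride synthesis genes Acacb, whose product makes the malonyl coenzyme A that restrains fat oxidation, rose 1.42-fold (adjusted p = 0.0475), the 1 gene to do so over all genes or over the list alone (median 0.25, adjusted p = 0.0171; adjusted p = 0.373 with an estimated correlation). Ppara, the nuclear receptor that switches on fatty acid oxidation during fasting, rose from 81.8 ± 5.97 to 110 ± 2.99 CPM (SD, n = 3 each; adjusted p = 0.0297), likewise the 1 gene of 24 in its list (median 0.099, adjusted p = 0.0207; adjusted p = 0.571 with an estimated correlation). No gene passed, over all genes or over the list alone, among 20 of insulin signalling (median 0.11, adjusted p = 0.023; adjusted p = 0.373 with an estimated correlation), 28 of the respiratory chain (0.083, adjusted p = 0.023; adjusted p = 0.571 with an estimated correlation) or 17 of the circadian clock (0.16, adjusted p = 0.0207; adjusted p = 0.249 with an estimated correlation). With library totals the medians of the urea (-0.0038), oxidation (-0.046), insulin (-0.041) and respiratory (-0.066) lists lay below 0, and those of the fatty acid synthesis and circadian lists were 0.094 and 0.0034. Without TOX3-activated library 2 the synthesis median was 0.11, without TOX3-activated library 3 the oxidation median was 0.035, and without TOX3-activated library 1 the respiratory median was 0.037. The insulin and respiratory lists missed the threshold with library totals (adjusted p = 0.0586 and 0.567), the insulin list with the correction for GC content and length (0.111) and the respiratory list with the filter of 5 CPM (0.0745). Without control 2 none of Prodh, Acacb and Ppara passed (adjusted p = 0.167, 0.165 and 0.135), and each of these lists except the urea list missed the threshold without at least 1 library.

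Cell cycle genes and targets of p53 also lay lower in TOX3-activated liver. The replication helicase genes Mcm3 (1.64-fold lower, adjusted p = 0.0322) and Mcm6 (1.78-fold lower, adjusted p = 0.0356) were the 2 of 24 cell cycle genes that fell over all genes, and 6 fell when adjusted over the list alone. Mcm6 went from 25.9 ± 1.21 to 14.5 ± 4.02 CPM (SD, n = 3 each). Aurkb (-1.20, SE 0.30, adjusted p = 0.0707) and Mcm2 (-0.73, SE 0.20, adjusted p = 0.102) did not pass, and the list had a median of -0.35 (adjusted p = 5.27e-06, or adjusted p = 0.357 with an estimated correlation). It did not pass by fry (0.0882), and its median was -0.22 without TOX3-activated library 1. All 14 p53 targets lay below 0 (median -0.35, adjusted p = 7.08e-05; adjusted p = 0.0826 with an estimated correlation), 0 of them passing over all genes or over the list alone; examples are Zmat3 (-0.36, SE 0.11) and Ccng1 (-0.34, SE 0.11). Neither Mcm3 nor Mcm6 passed without any 1 of controls 1 to 3 or TOX3-activated libraries 1 and 2.

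The other lists did not pass as a whole. Acute phase genes had 0 passing over all genes, and 3 that rose and 4 that fell when adjusted over the list alone (median 0.059, mean -0.13, adjusted p = 0.627); the list passed without control 1 (adjusted p = 0.0229). Among 13 male-biased genes Slco1a1 rose and Mup20, a urinary pheromone protein, fell from 9023 ± 816 to 5584 ± 371 CPM (SD, n = 3 each; log2 fold change -0.69, SE 0.12, adjusted p = 0.0199), while 3 rose and 1 fell when adjusted over the list alone (list adjusted p = 0.238, 0.0239 with library totals and 0.0108 without TOX3-activated library 3). Mup20 belongs to a cluster of near-identical genes and had fractional counts in 5 libraries, so its change is uncertain. No gene passed among 19 of glycolysis (list adjusted p = 0.957), 22 of cholesterol synthesis (0.241, and 0.000456 without TOX3-activated library 3), 20 of endoplasmic reticulum stress (0.092) or 4 female-biased genes (0.366), over all genes or over the list alone. Endoplasmic reticulum stress passed without control 2 (0.0315) or TOX3-activated library 2 (0.0409) and with the filter of 5 CPM (0.0473), and the female-biased list passed without the expression filter (median -0.88, adjusted p = 0.0314). Of 14 glycogen genes 0 passed over all genes and 2 rose when adjusted over the list alone (0.441). The 4 tested genes of the Y chromosome, which check for mixed sexes, did not differ beyond the test (0.97), with Ddx3y at 78.1 CPM in controls and 75.3 CPM in TOX3-activated liver. Only 2 pancreas and adipose markers were tested, too few for a list test, and neither passed over all genes. With library totals the medians of the acute phase (-0.078), male-biased (-0.061), cholesterol (-0.099), endoplasmic reticulum stress (-0.041) and glycogen (-0.12) lists turned from above to below 0.

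**Figure D3:**
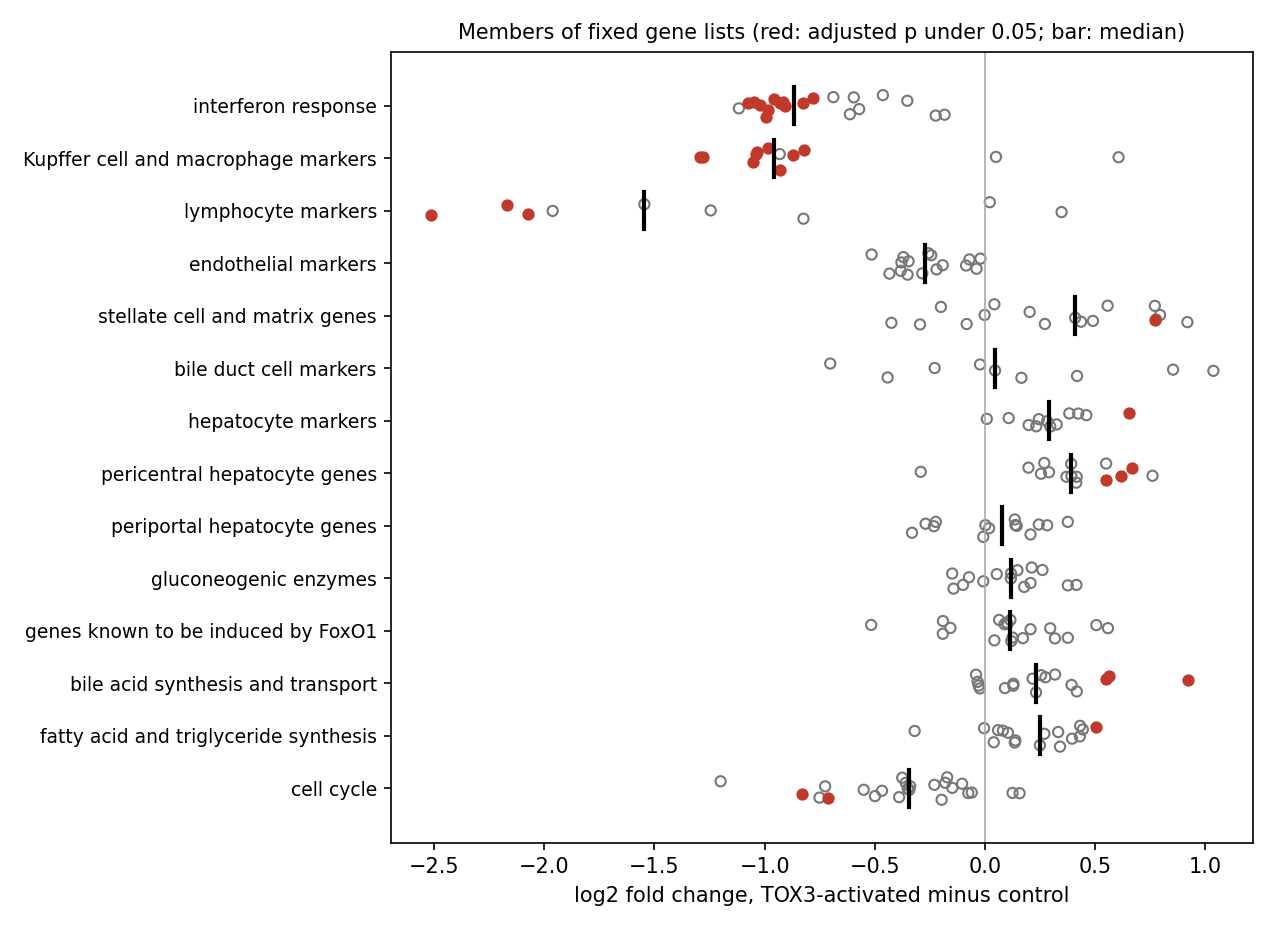
Log2 fold change of TOX3-activated minus control liver (x axis) for the tested members of 14 fixed gene lists (y axis, 1 row per list); each circle is 1 gene, filled red where its adjusted p is below 0.05, and the bar is the list median. Interferon, Kupffer cell and lymphocyte lists have medians of -0.87, -0.96 and -1.55, and gluconeogenic and FoxO1-induced genes both have a median of 0.12.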

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

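Of 45 named genes that passed, 13 passed in every alternative fit that tested them, 32 missed the threshold in at least 1 and 0 reversed, while 26 named genes that had not passed did so in at least 1. The filter of 5 CPM removed 2 of the 13, Slfn4 and Cd300e, and the fold threshold was applied to counts of genes only. Of 18 lists that passed, 9 kept both the threshold and the sign of the median in every alternative that tested them, other than the set tests; the voom and other quasi-likelihood fits could not move a list's p and are no evidence here. The lymphocyte list, 1 of the 9, had too few genes left under the filter of 5 CPM. The cause of a difference was not tested, except that leaving out a library leaves fewer samples and the filters change the number of genes. With library totals in place of TMM, 610 genes changed, 40 rose and 570 fell, and the medians below turned from above to below 0, as any median less than the shift of -0.15 in all genes must: gluconeogenic enzymes -0.031, their regulators -0.060, FoxO1-induced genes -0.039, glycogen -0.12, cholesterol -0.099, fatty acid oxidation -0.046, insulin signalling -0.041, male-biased genes -0.061, endoplasmic reticulum stress -0.041, acute phase -0.078, respiratory chain -0.066, urea cycle -0.0038, periportal genes -0.072 and bile duct -0.10. So did Ppargc1a (-0.037), Atp5b (-0.0068), Ndufa9 (-0.033) and Atp5a1 (-0.023).

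Without the filter 415 genes changed, 141 of them upward. The filter of 5 CPM gave 170, with 39 that rose, a median of 0.099 for genes known to be induced by FoxO1, which passed (adjusted p = 0.0432), and medians of 0.053 for glycolysis and 0.069 for xenobiotic genes. DESeq2, with its own scaling, gave 574 (241 rose, 333 fell). In simulated data 14.7% of its calls were false with the spread set gene by gene, against 8.21% for the main test. With the spread on the mean trend these shares were 4.23% and 3.67%. Voom gave 146 that rose, and the fold threshold of 1.5 left 42 that rose. The correction for GC content and length, added with the other quasi-likelihood estimator after seeing the data, gave 0.16 for gluconeogenic enzymes (adjusted p = 0.0484), 0.0042 for glycolysis, 0.037 for xenobiotic genes and 0.085 for the sex check. With an estimated correlation 0 lists passed, the interferon median of -0.87 having an adjusted p of 0.0826 and the Kupffer cell median of -0.96 one of 0.124. Fry passed 10 lists, among them the FoxO1-induced (median 0.12, adjusted p = 0.0199) and TOX family (0.0087) lists, which camera had not passed. Of the lists that camera passed, fry did not pass cell cycle (0.0882), endothelial (0.24), stellate (0.254), red blood cell (0.225) and urea (0.225). Nor did it pass fatty acid synthesis (0.189), oxidation (0.339), insulin signalling (0.189), the respiratory chain (0.30) and the circadian clock (0.125).

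Leaving out 1 library at a time gave 52 to 341 genes changed, 6 to 150 that rose and 46 to 191 that fell. The medians ran from 0.047 to 0.16 for gluconeogenic enzymes, 0.11 to 0.14 for FoxO1-induced genes, -0.0034 to 0.12 for regulators, -0.054 to 0.015 for glycolysis, -0.019 to 0.11 for glycogen, -0.12 to 0.12 for xenobiotic genes, -0.060 to 0.29 for acute phase, -0.078 to 0.042 for the sex check, -0.19 to 0.047 for the TOX family, -0.0068 to 0.35 for male-biased genes, -0.086 to 0.20 for cholesterol and -0.090 to 0.22 for bile duct. Ppargc1a ran from -0.12 to 0.31, Tox from -0.34 to 0.023 and Tox4 from -0.11 to 0.075. The planned pseudocount alternative was for normalized values only and was not run, the prior count of 2 in the list tests was not varied, and no replicate block was fitted because the title numbers are not shared between groups. At this depth the smallest simulated changes were recovered in 5.9% of cases, or 8.89% with the spread on the mean trend.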

Other observations

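Some genes outside the fixed lists, picked from those that fell after their values were seen, are known from immune cells. They were not tested as a group. Ptprc, the surface phosphatase carried by white blood cells, went from 15.9 ± 1.02 to 6.80 ± 0.554 CPM (SD, n = 3 each; log2 fold change -1.22, adjusted p = 0.00131). Fcgr4, an antibody receptor (-1.65, adjusted p = 0.00131), Ctss, a lysosomal protease of antigen-presenting cells (-1.09, adjusted p = 0.00287), and Cybb, the catalytic subunit of the phagocyte oxidase (-1.04, adjusted p = 0.00336), fell too. Of the 40 genes that passed in all 14 alternative fits 35 fell, and the 5 that rose were Tox3, Reln, Tnxb, Slc6a9 and Gabbr2. Tnxb, which encodes a matrix protein, went from 12.5 ± 1.22 to 24.9 ± 3.89 CPM (SD, n = 3 each; log2 fold change 0.99, adjusted p = 0.00689).

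The tests of hepatocyte share, of equal macrophage loss, of precision and of zonation were chosen after the results were seen, and the correction for GC content and length was added after the data were seen.

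Of 12 Kupffer cell and macrophage markers 9 fell, and the list passed by camera but not with an estimated correlation (adjusted p = 0.124). A larger share of hepatocyte RNA alone would lower other cell types alike. The pooled endothelial, stellate and bile duct markers lay 0.903 higher on the log2 scale (permutation p over genes 8e-05, which does not treat samples as replicates). These pooled lists differed, with medians of -0.27 for endothelial, 0.41 for stellate and 0.045 for bile duct markers. A part for hepatocyte share in the fall stays open. After the correction for GC content and length the macrophage median was -0.936 (adjusted p = 1.32e-12), which argues against that bias. An equal loss of all macrophages may underlie it, and stays open: heterogeneity between markers had a p of 0.00028 with the standard errors taken as known, but 0.014 with their estimation allowed for, between the bounds set. Fewer macrophages, less expression per cell, and an effect of TOX3 activation itself were not told apart.

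The gluconeogenic and FoxO1-induced lists did not pass, with 10 of 15 and 15 of 19 genes above 0. The FoxO1-induced list had an adjusted p of 0.014 by camera without control 1 and at lowest 0.109 without another control. The list's median log2 CPM, centred on all libraries, was highest among controls in control 1 (0.0544 against -0.0755 and -0.0625). Its removal therefore favours a rise, so the test cannot decide whether control 1 was in another metabolic state. Among controls, control 1 was highest for Igfbp1, Irs2 and Pdk4 but lowest for Foxo1, Pck1 (2240 against 2770 and 2710 CPM) and Ppargc1a. That library was singled out from its own values, so this is no ground for leaving control 1 out. The gluconeogenic list also passed without TOX3-activated library 3 (0.0445) and, with all 6 libraries, after the correction for GC content and length (0.0484). Precision for single genes may also have been too low, as the smallest simulated changes were recovered in 5.9% of cases (8.89% with the spread on the mean trend). A simulated list of 16 genes with the same change passed all 3 set tests (highest adjusted p = 0.0392). Its genes were drawn independently, without the correlation that genes of real lists can have, so this does not show that real lists would pass. Lists with changes as small as these were not simulated. An effect of TOX3 activation on these genes stays open.

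The pericentral list passed by camera, with 3 of 15 genes rising, but not with an estimated correlation (adjusted p = 0.0826), and the periportal list did not pass. A larger hepatocyte share alone would raise both alike, but the pericentral median was 0.315 higher (permutation p over genes 0.00131, which does not treat samples as replicates). A part for hepatocyte share in the rise stays open. After the correction for GC content and length the pericentral median was 0.428 (adjusted p = 3.72e-06). A shift of zonation may be involved, and would be expected to lower periportal genes. The periportal list holds Pck1 and G6pc (log2 fold changes 0.38 and 0.21), so this test is not separate from the genes of glucose production. The periportal median was 0.0766 (SE 0.0588), too close to 0 for its spread to decide, and -0.072 with library totals. A shift of zonation therefore stays open. TOX3 activation as a cause was not tested apart from these.

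Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real one, gave as many as 272 genes, the highest other count being 1. For gene lists again only 1 of 10, the real one, reached 18, with 13 as the highest other count, so camera at the preset correlation also passes many lists between mixed groups. Every other split mixed the groups unevenly, so part of any real difference stayed between its groups and the rest widened the spread within them. The other counts therefore do not measure how many genes or lists pass without a difference. These splits are too few for a share below 0.05. Of the other 9 splits, the interferon list passed in 5, the Kupffer cell list in 4 and the cell cycle list in 6. Some lists that passed had a lower adjusted p by camera in a mixed split than in the real one. These were the endothelial (2.91e-06 against 0.000605), urea (2.15e-07 against 0.000605), red blood cell (2.99e-05 against 0.00335) and oxidation (3.91e-06 against 0.0207) lists. The stellate, respiratory chain, fatty acid synthesis and insulin signalling lists did so too. The other lists that passed had their lowest in the real split.

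Families of genes that share a symbol stem, 210 with at least 8 tested members, were tested after the data were seen. At the preset correlation 7 passed, and 0 with an estimated correlation. The Ifi (median -0.80, adjusted p = 4.53e-11) and Gbp (-0.92, adjusted p = 5.04e-08) families of interferon-inducible genes lay lower, as did Clec lectins (-0.64, adjusted p = 3.07e-05), Tlr receptors (-0.59, adjusted p = 0.000403) and Olfr receptors (-0.26, adjusted p = 0.0477). The collagens (0.49, adjusted p = 0.0477) and the Mup family (0.51, adjusted p = 0.000533) lay higher. Of 20 Mup genes 19 had fractional counts, as had 28 of 32 Olfr genes, so these are uncertain.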
